A study of Rattus norvegicus with 50 samples.

How the data were processed

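RNA was measured in 50 libraries of rat placenta from control and ITE-treated pregnancies with female or male fetuses (13 control female, 8 ITE female, 16 control male and 13 ITE male). Per the labels' protocols, total RNA was extracted with an RNeasy kit, only RNA of high integrity was used, and libraries were made with a TruSeq RNA kit and random primers. Per the submitters' processing notes, the tools were bcl2fastq 2.20.0.422, STAR 2.5.3a, RSEM and edgeR 3.28.0, with genome build Rnor_6.0. The version of RSEM, the annotation release and any filters of the authors are not given in the sources used here. The deposited table holds expected counts per gene (RSEM estimated counts), which the authors left without normalization, and 100% of its values are whole numbers. It has 32883 Ensembl genes with symbols. In 196 cases a symbol stood on more than 1 gene, and 33 genes had none. All 50 columns were used, and groups came from the labels' treatment and fetal sex.

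Total counts ran from 20772997 to 42492645 per library. Genes with low counts were removed with filterByExpr of edgeR 4.0.16 on the 4 groups, which left 15269 genes. Counts were scaled by TMM factors and fitted with 1 coefficient per group over all 50 libraries, so that the groups share 1 estimate of the spread. Quasi-likelihood F tests gave ITE against control in females, in males and in their mean, the interaction of sex and treatment (female minus male effect), and male against female in controls and in ITE. The p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The SE of a log2 fold change is its absolute value over the square root of F. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. Before the tests on these data, the same code was tested on simulated data with 200 of 15269 genes changed. It recovered 73.1% of genes changed 1.5-fold and 92.5% of those changed 2-fold in the female comparison, 86.6% and 94% in the male one, 64.2% and 86.6% in the interaction and 77.6% and 97% between sexes in ITE. False calls were 5.41% to 6.7% of the calls, and camera called none of 40 unchanged lists. The simulated genes and libraries were independent of each other, with 1 spread per gene for all 4 groups. Genes of real lists were correlated, with an estimate of 0.513 for endothelial and 0.628 for erythroid markers in females. The simulation therefore does not show how often camera calls unchanged lists in these data.

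The choices that follow were made before the data were examined. There were 34 gene lists of pathways and cell types, with 547 entries of 516 distinct genes, so some genes are on more than 1 list, and 441 of them were tested. Lists with at least 3 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists, beside camera with a correlation estimated per list and fry. Listed genes were matched by symbol, or else by a synonym in the RefSeq gene table of assembly GRCr8. Some listed genes, such as Xist, Pecam1 and H19, could not be tested because the table has no such symbol or too few counts. Named genes were, per treatment comparison and for controls between sexes, the 8 with the largest log2 fold change in each direction (adjusted p under 0.05, a gene symbol, and a mean of 1 CPM or more in a group) and the 4 with the smallest p in each direction. To these came the 4 members with the smallest p of each list called by camera, and always Cyp1a1, Cyp1b1, Ahrr, Tiparp and Nqo1. For the interaction they were the 6 genes with the smallest p.

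Scores of 13 cell type lists (mean log2 CPM of the tested members) were compared between ITE and control within each sex by two-sided permutation tests with scipy 1.17.1, exact for females and with 100000 resamples for males, adjusted over 26 tests. Female and male fold changes were compared by correlation across genes and by overlap of the called genes. Alternatives were RLE size factors, DESeq2 1.42.0, no filter, a filter at a mean of 5 CPM, the replicate number as a block, limma-voom with runs of label numbers as a random block, limma-voom with quality weights, tissue scores as covariates, a fit of only the groups compared, and leaving out each library in turn. Scaling by total counts, leaving out the library labelled control male 12, endothelial and erythroid scores as covariates, sums per run and a fixed term for runs were added after seeing the data. Counts of called genes and lists were compared with 100 random arrangements of the libraries. No coordinates are given, because the table rests on another genome build than the reference at hand. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.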

Results

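Gene expression was measured by RNA sequencing in 50 libraries of rat placenta. The dams had received ITE, an endogenous ligand of the aryl hydrocarbon receptor (AhR, a ligand-activated transcription factor), or were controls. Dose, timing and vehicle are not given in the sources used here. The labels gave treatment and fetal sex, with 13 control female, 8 ITE female, 16 control male and 13 ITE male libraries. Total counts ran from 20772997 to 42492645 per library. Their means were 30429516 ± 4268255 in control female (SD, n = 13), 28688542 ± 4450902 in ITE female (n = 8), 28412943 ± 3491525 in control male (n = 16) and 27807992 ± 3065489 in ITE male libraries (n = 13). After a filter on low counts, 15269 genes were tested. The dam and litter of each placenta are not given either, so p-values measure the spread between these libraries.

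The first principal component of log2 CPM held 31.8% of the variance and parted the treatments. Its means were -29.3 ± 6.4 in control female, -30.7 ± 7.2 in control male, 30.9 ± 29.6 in ITE female and 48.1 ± 23.5 in ITE male libraries (SD). The ITE libraries were spread unevenly along it. In 6 of them, 4 female and 2 male, scores ran from -6.86 to 11.5, and in the other 15, 4 female and 11 male, from 47.6 to 68.2. The 6 were ITE female libraries 3, 5, 6 and 7 and ITE male libraries 4 and 13. Cyp1a1, a cytochrome P450 under direct AhR control, was at 49.5 to 171 CPM in the 6 and at 2.16 to 11.8 CPM in the 15. Endothelial marker scores (mean log2 CPM) were 3.89 to 4.54 in the 6 and 2.0 to 3.58 in the 15, and erythroid scores 2.8 to 3.76 and 1.41 to 2.4. The sets were parted by the component of these same log2 CPM values. Differences between them in genes and scores therefore follow in part from that choice.

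The first question was what ITE changed in placentas of female fetuses. The AhR targets Cyp1a1, Cyp1b1 and Ahrr rose steeply, whereas 13 of 14 tested erythroid, 15 of 18 endothelial and 8 of 11 myometrial markers fell. With an estimated correlation camera called none of these lists. Cyp1a1 (ENSRNOG00000019500) went from 1.30 ± 0.883 CPM in controls (SD, n = 13) to 53 ± 58.5 CPM with ITE (n = 8), a log2 fold change of 5.36 (SE 0.67, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 2.35e-08). Cyp1b1 (ENSRNOG00000040287), a related enzyme, went from 1.15 ± 0.479 to 25.2 ± 19.4 CPM (log2 fold change 4.45 ± 0.33, SE). Ahrr (ENSRNOG00000014721), which encodes the AhR repressor, went from 0.264 ± 0.138 to 4.86 ± 2.65 CPM (4.16 ± 0.32). Of the 15269 genes, 6484 passed an adjusted p of 0.05 in edgeR, 3438 higher and 3046 lower with ITE. Among them 371 higher and 676 lower genes changed at least 2-fold. In limma-voom with runs of label numbers as a random block 5653 genes passed. When scaled by total counts instead of TMM factors, 1730 genes were higher and 4625 lower, with the median log2 fold change of all genes at -0.105 in place of 0.024. With scores of 4 tissue lists as covariates 460 genes passed in edgeR, and with endothelial and erythroid scores 809. Myometrial, junctional zone, endothelial and erythroid scores themselves differed by treatment. As covariates they can take up the ITE effect, so the drop cannot part tissue make-up from it.

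Values after gene symbols here and below are log2 fold changes ± SE. Further large rises in female placentas were those of Slc5a8 (3.91 ± 0.59), a monocarboxylate transporter gene, the potassium channel gene Kcna2 (3.14 ± 0.37), and Ms4a7 (3.29 ± 0.24). Kcng1, another potassium channel gene, went from 0.261 ± 0.202 to 2.85 ± 5.67 CPM (3.43 ± 0.63), and without ITE female library 4 its log2 fold change was 1.69 (adjusted p = 0.013 in edgeR). Uchl3 (3.16 ± 1.18) rose with an adjusted p of 0.0268 in edgeR. Without control female library 1 its value was 7.24, and without ITE female library 5 or 6 it no longer passed (adjusted p of 0.0739 to 0.083 in edgeR). Tnfrsf21 (1.95 ± 0.17) was among the rises with the smallest p. Large falls were those of Tmem255a (-3.05 ± 0.39), Abcc8 (-2.99 ± 0.71), Hbg1 (-2.90 ± 0.60), Klf1 (-2.79 ± 0.35), Ace (-2.72 ± 0.41), Hba-a2 (-2.69 ± 0.42), Slc6a19 (-2.63 ± 0.66) and Zcchc12 (-2.61 ± 0.47), with adjusted p of 0.00118 or less in edgeR. Abcc8 was at -3.64 without ITE female library 3. Ace encodes angiotensin-converting enzyme, Abcc8 a subunit of a potassium channel, and Slc6a19 a neutral amino acid transporter. Mmp14, a membrane-bound matrix metalloproteinase, had the smallest p and went from 149 ± 14.9 to 66.7 ± 9.29 CPM (-1.16 ± 0.074). The caveolar gene Cavin1 (-1.01 ± 0.093), C1qtnf2 (-2.16 ± 0.20) and Tspan3 (-1.09 ± 0.10) also fell.

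Gene lists, comparisons, tests and the rule for naming genes were set before the data were examined. Among AhR target genes, 6 of 9 tested genes rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.000932, and adjusted p = 0.119 with an estimated correlation). Nqo1 (ENSRNOG00000012772), a quinone reductase, rose from 18.8 ± 2.73 to 43.9 ± 12.1 CPM (1.23 ± 0.13), and Tiparp, an AhR-induced ADP-ribosyltransferase, rose by 0.34 (SE 0.090). The listed targets that fell were Slc7a5 (-0.77 ± 0.15) and Xdh (-0.61 ± 0.15), which encode an amino acid transporter and xanthine dehydrogenase. Members that went against their list, and members of lists that camera did not call, are named here and below after their values were seen. Among NRF2 oxidative stress genes, 6 of 11 tested genes rose and 1 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.0491, and adjusted p = 0.411 with an estimated correlation). Txnrd1 (0.77 ± 0.13), G6pd (0.47 ± 0.089) and Prdx1 (0.39 ± 0.11) rose, while Gclc, a subunit of the enzyme that starts glutathione synthesis, fell (-0.35 ± 0.10).

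**Figure D1:**
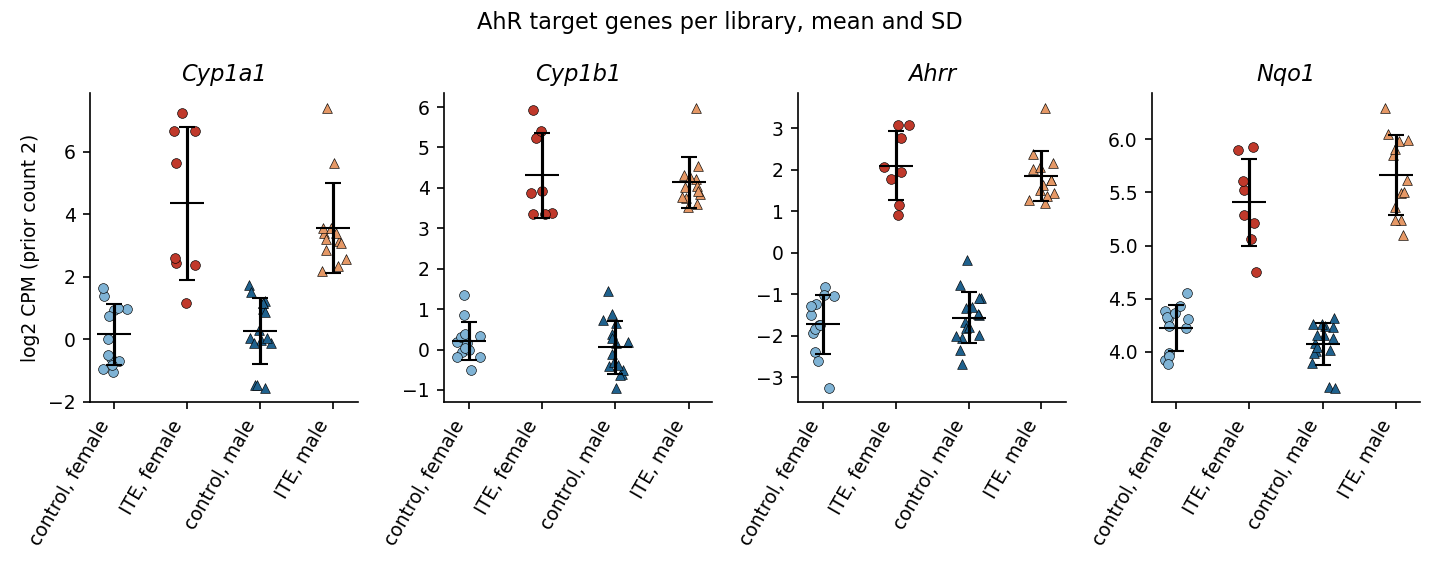
Level (log2 CPM, prior count of 2) of Cyp1a1, Cyp1b1, Ahrr and Nqo1 in each of the 50 libraries, by group; points are libraries, wide lines group means and whiskers SD. For Cyp1b1 the lowest of 21 ITE libraries had 10.1 CPM and the highest control library 2.64 CPM.

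Many red cell and vessel genes fell in female placentas. Among erythroid markers, 13 of 14 tested genes fell and none rose (13 adjusted over the list alone, camera adjusted p = 6.47e-10, and adjusted p = 0.119 with an estimated correlation). Klf1, an erythroid transcription factor, the haemoglobin chaperone gene Ahsp (-2.11 ± 0.29) and Hba-a1 (-2.50 ± 0.38) were among them. Hba-a1 and Hba-a2 are near-identical copies, so their separate values are uncertain. Among endothelial markers, 15 of 18 tested genes fell and 1 rose (16 and 1 adjusted over the list alone, camera adjusted p = 6.74e-07, and adjusted p = 0.204 with an estimated correlation). Tie1 (-1.37 ± 0.20), Mmrn2 (-1.73 ± 0.27), Eng (-0.98 ± 0.15) and Sox17 (-1.35 ± 0.23) fell, and Cdh5, an endothelial cadherin, rose (0.30 ± 0.10). Among angiogenic ligands and receptors, 12 of 21 tested genes fell and 1 rose (15 and 1 adjusted over the list alone, camera adjusted p = 8.67e-06, and adjusted p = 0.119 with an estimated correlation). Ephb4 (-1.56 ± 0.21), Notch4 (-1.50 ± 0.23) and Vegfa (-0.85 ± 0.14) fell, and Vegfb (0.47 ± 0.13) rose. Among vasoactive genes, 9 of 16 tested genes fell and 3 rose (11 and 3 adjusted over the list alone, camera adjusted p = 0.00659, and adjusted p = 0.206 with an estimated correlation). Ace, the angiotensin receptor gene Agtr1a (-1.26 ± 0.19), Gucy1b1 (-1.02 ± 0.18) and Pde5a (-0.75 ± 0.14) fell, and Ednrb (0.81 ± 0.17), Ptgs1 (0.69 ± 0.17) and Adm (0.44 ± 0.18) rose. Among pericyte and vascular smooth muscle markers, 5 of 11 tested genes fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.00149, and adjusted p = 0.183 with an estimated correlation). Tagln (-1.57 ± 0.15), Cox4i2 (-1.54 ± 0.21) and Notch3 (-1.63 ± 0.29) fell, and Pdgfrb (0.57 ± 0.11) rose. Among myometrial smooth muscle markers, 8 of 11 tested genes fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 7.59e-05, and adjusted p = 0.119 with an estimated correlation). Lmod1 (-1.94 ± 0.26), Mylk (-0.998 ± 0.14), Actg2 (-1.52 ± 0.24) and Myocd (-1.35 ± 0.25) fell, and Sorbs1 (0.21 ± 0.078) rose. In edgeR, Sorbs1 no longer passed without any of ITE female libraries 3, 5 and 7 (adjusted p of 0.0517 to 0.119), nor Adm without any of 18 libraries (0.0505 to 0.446).

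Many trophoblast genes of the junctional zone, the endocrine layer of the rat placenta, rose in female placentas. Among prolactin family genes, 15 of 21 tested genes rose and none fell (17 adjusted over the list alone, camera adjusted p = 4.14e-08, and adjusted p = 0.115 with an estimated correlation). Among junctional zone markers, 13 of 20 tested genes rose and none fell (14 adjusted over the list alone, camera adjusted p = 3.74e-06, and adjusted p = 0.141 with an estimated correlation). Among giant and invasive trophoblast markers, 10 of 12 tested genes rose and none fell (11 adjusted over the list alone, camera adjusted p = 3.79e-05, and adjusted p = 0.0726 with an estimated correlation). Tpbpa, the classical spongiotrophoblast marker, went from 13000 ± 4120 to 25600 ± 4550 CPM (0.98 ± 0.16). Prl2a1 (1.13 ± 0.11), Prl4a1 (1.002 ± 0.13), Prl6a1 (1.32 ± 0.20), Prl8a5 (0.82 ± 0.14), Prl3d4 (1.27 ± 0.19), Prl7d1 (1.44 ± 0.22) and Plau (0.75 ± 0.15) also rose. The prolactin genes are close paralogs, so reads shared between them make single members uncertain. Of the labyrinth trophoblast markers, 1 of 14 tested genes was higher and 4 lower (1 and 4 adjusted over the list alone), and camera gave the list an adjusted p of 0.14. The lower ones were Slc13a4 (-1.98 ± 0.53), Gcm1 (-1.75 ± 0.41), Gcgr (-1.42 ± 0.23) and Slc16a3 (-1.25 ± 0.23), and the higher one Ctsq (0.43 ± 0.17). Gcm1 is a regulator of syncytiotrophoblast formation. In edgeR, Ctsq no longer passed without any of 5 libraries, ITE female 3 and 5 and control female 9, 10 and 13 (adjusted p of 0.0536 to 0.0824).

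Many stress, interferon and clock genes also rose in female placentas. Among unfolded protein response genes, 11 of 16 tested genes rose and none fell (12 adjusted over the list alone, camera adjusted p = 3.74e-06, and adjusted p = 0.183 with an estimated correlation). Xbp1 (0.55 ± 0.054), Calr (0.53 ± 0.067), Hsp90b1 (0.56 ± 0.081) and Ddit3 (0.46 ± 0.079) were among them. Among interferon response genes, 12 of 18 tested genes rose and none fell (12 adjusted over the list alone, camera adjusted p = 0.000825, and adjusted p = 0.401 with an estimated correlation). Mx1 (1.94 ± 0.32), Cxcl10 (2.08 ± 0.42), Isg15 (0.76 ± 0.17) and Gbp2 (0.86 ± 0.20) led them. Among circadian clock genes, 7 of 14 tested genes rose and none fell (7 adjusted over the list alone, camera adjusted p = 0.00669, and adjusted p = 0.119 with an estimated correlation). Per3 (0.75 ± 0.11), Bhlhe41 (0.59 ± 0.093), Nr1d2 (0.52 ± 0.083) and Per2 (0.49 ± 0.10) rose. Among mitochondrially encoded transcripts, 11 of 13 tested genes rose and none fell (11 adjusted over the list alone, camera adjusted p = 4.83e-05, and adjusted p = 0.257 with an estimated correlation). Mt-nd2 (0.65 ± 0.11), Mt-cyb (0.51 ± 0.094), Mt-nd4 (0.73 ± 0.14) and Mt-atp6 (0.46 ± 0.089) rose. Among nuclear oxidative phosphorylation genes, 10 of 20 tested genes fell and none rose (10 adjusted over the list alone, camera adjusted p = 0.00544, and adjusted p = 0.374 with an estimated correlation). The falls were small, such as those of Cyc1 (-0.44 ± 0.054), Atp5f1a (-0.26 ± 0.045), Ndufs3 (-0.34 ± 0.066) and Ndufv1 (-0.43 ± 0.091). Among X-linked sex-biased genes, 5 of 7 tested genes rose and none fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0491, and adjusted p = 0.257 with an estimated correlation). Ogt (0.30 ± 0.060), Kdm6a (0.27 ± 0.059), Ddx3x (0.21 ± 0.053) and Eif2s3 (0.22 ± 0.057) were among them.

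Camera called none of the remaining lists in female placentas, with adjusted p from 0.0631 to 0.952. Of the macrophage markers, 9 of 13 tested genes were higher and 2 lower (9 and 2 adjusted over the list alone). The lower ones were Cd163, a haemoglobin scavenger receptor (-1.71 ± 0.37), and Mrc1 (-0.65 ± 0.16). For inflammatory cytokines and chemokines, 8 of 17 genes were higher and 1 lower (8 and 1 adjusted over the list alone), with Ccl2 (2.09 ± 0.31) higher and Nfkbia (-0.36 ± 0.12) lower. 4 of 9 neutrophil markers were higher and 1 lower (4 and 1 adjusted over the list alone), the latter being Camp (-1.28 ± 0.46). 4 of 12 immediate early genes were higher and 3 lower (4 and 3 adjusted over the list alone), with Egr1 (1.21 ± 0.23) higher and Fos (-0.61 ± 0.13) lower. 3 of 11 natural killer cell markers were higher and 1 lower (3 and 1 adjusted over the list alone), the latter being Eomes (-0.77 ± 0.24), and none of 5 lymphocyte markers was higher or lower (0 and 0 adjusted over the list alone). Of the imprinted placental genes, 1 of 13 genes was higher and 6 lower (1 and 7 adjusted over the list alone), with Igf2, a fetal growth factor gene, going from 2630 ± 216 to 1760 ± 391 CPM (-0.58 ± 0.10). Of the nutrient and drug transporters, 2 of 20 genes were higher and 6 lower (2 and 6 adjusted over the list alone), with Slc22a3, an organic cation transporter gene, at -1.54 ± 0.42. 6 of 12 steroid synthesis genes were higher and 2 lower (6 and 2 adjusted over the list alone), with the lipoprotein receptor gene Scarb1 (-1.04 ± 0.15) lower. 4 of 13 decidual markers were higher and 2 lower (4 and 2 adjusted over the list alone), with Igfbp1 (1.75 ± 0.59) higher and Bmp2 (-1.08 ± 0.18) lower. None of 14 yolk sac markers was higher and 2 lower (0 and 1 adjusted over the list alone), the latter being Apoa2 (-2.35 ± 0.73) and Ttr (-1.97 ± 0.72). 4 of 19 matrix genes were higher and 3 lower (4 and 3 adjusted over the list alone), and 7 of 17 hypoxia genes were higher and 4 lower (7 and 5 adjusted over the list alone). 4 of 18 cell cycle genes were higher and 2 lower (4 and 2 adjusted over the list alone), with Ccna2 (-1.40 ± 0.26) lower. 3 of 8 AhR pathway components were higher and 2 lower (4 and 4 adjusted over the list alone), with Ahr (-0.32 ± 0.12) and Arnt2 (-0.61 ± 0.15) lower, and none of 5 Y-linked genes was higher or lower (0 and 0 adjusted over the list alone). Median and mean differed in sign for AhR components (0.019 and -0.063), cell cycle (0.099 and -0.034) and matrix genes (-0.035 and 0.141), and for hypoxia genes camera pointed down at a median of 0.042. In edgeR, Ahr no longer passed without any of 6 libraries (adjusted p of 0.0517 to 0.096), and Apoa2 was at -2.93 without ITE female library 3.

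In placentas of male fetuses the AhR targets Cyp1b1, Cyp1a1 and Ahrr also rose. Of the tested list members, 13 of 14 erythroid and 15 of 18 endothelial markers fell, and 17 of 18 interferon and 10 of 17 inflammatory genes rose, though with an estimated correlation camera called none of these lists. Cyp1b1 went from 1.08 ± 0.576 CPM (SD, n = 16) to 19.8 ± 13.6 CPM (n = 13), a log2 fold change of 4.19 ± 0.29 (SE, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 4.76e-16). Cyp1a1 went from 1.43 ± 0.924 to 24.1 ± 45.5 CPM (4.08 ± 0.57) and Ahrr from 0.300 ± 0.177 to 3.94 ± 2.37 CPM (3.71 ± 0.28). The chemokine gene Cxcl10 went from 1.13 ± 0.405 to 17 ± 24.2 CPM (3.92 ± 0.37). Without ITE male library 13 Cyp1a1 was at 3.05, and without ITE male library 3 Cxcl10 was at 3.29. In edgeR, 8173 genes passed an adjusted p of 0.05, 4374 higher and 3799 lower, with 550 and 1011 of them changed at least 2-fold. In limma-voom with runs of label numbers as a random block 6709 genes passed. When scaled by total counts, 2680 were higher and 5267 lower. With scores of 4 tissue lists as covariates 170 genes passed in edgeR, and with endothelial and erythroid scores 305. These scores differed by treatment in males too, except the yolk sac one, so the same limit holds.

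Other large rises in male placentas were those of the cytokine gene Il24 (5.24 ± 0.55), Kcng1 (4.57 ± 0.60), the chemokine gene Ccl12 (3.71 ± 0.36) and Lypd5 (3.65 ± 0.67). Nqo1 went from 16.9 ± 2.19 to 52.2 ± 13.6 CPM (1.63 ± 0.11) and was, with Ms4a7 (3.58 ± 0.21) and Tnfrsf21 (2.04 ± 0.15), among the rises with the smallest p. Large falls were those of Hbg1 (-4.33 ± 0.56), Cldn8 (-4.17 ± 0.69), Tmem255a (-4.01 ± 0.34), Car1 (-3.87 ± 0.51), Ace (-3.46 ± 0.35), Abcc8 (-3.43 ± 0.61), Chga (-3.39 ± 0.36) and Kel (-3.36 ± 0.35), with adjusted p of 5.31e-06 or less in edgeR. Hbg1 was at -5.35 without ITE male library 4 and Chga at -3.99 without ITE male library 13. Hbg1, Car1 and Kel encode a globin, a red cell carbonic anhydrase and a red cell surface protease. Mmp14 went from 160 ± 12.1 to 78.3 ± 10.7 CPM (-1.03 ± 0.060), and Tspan3 (-1.24 ± 0.085), Cybrd1 (-1.52 ± 0.11) and Prx (-2.61 ± 0.19) followed by p.

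Many AhR target and oxidative stress genes rose in male placentas, and many red cell and vessel genes fell. Among AhR target genes, 6 of 9 tested genes rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.00817, and adjusted p = 0.141 with an estimated correlation). Tiparp rose by 0.34 (SE 0.075), and Slc7a5 (-0.97 ± 0.12) and Xdh (-0.90 ± 0.13) fell. Among NRF2 oxidative stress genes, 8 of 11 tested genes rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00183, and adjusted p = 0.17 with an estimated correlation). Txnrd1 (1.03 ± 0.11) and Hmox1 (0.99 ± 0.13) rose and Gclc (-0.64 ± 0.083) fell. Among erythroid markers, 13 of 14 tested genes fell and none rose (13 adjusted over the list alone, camera adjusted p = 2.31e-11, and adjusted p = 0.141 with an estimated correlation). Ahsp (-2.90 ± 0.24), Slc4a1 (-3.14 ± 0.33), Epb42 (-3.02 ± 0.32) and Hba-a1 (-2.79 ± 0.31) fell. Among endothelial markers, 15 of 18 tested genes fell and none rose (15 adjusted over the list alone, camera adjusted p = 6.34e-08, and adjusted p = 0.141 with an estimated correlation). Tie1 (-1.46 ± 0.16), Mmrn2 (-1.93 ± 0.22), Eng (-0.94 ± 0.13) and Ptprb (-1.82 ± 0.26) fell. Among angiogenic ligands and receptors, 14 of 21 tested genes fell and none rose (14 adjusted over the list alone, camera adjusted p = 9.05e-07, and adjusted p = 0.141 with an estimated correlation). Ephb4 (-1.72 ± 0.17), Angpt1 (-1.84 ± 0.18), Vegfa (-1.03 ± 0.11) and Efnb2 (-0.996 ± 0.11) fell. Among vasoactive genes, 9 of 16 tested genes fell and 3 rose (9 and 3 adjusted over the list alone, camera adjusted p = 0.00204, and adjusted p = 0.141 with an estimated correlation). Ptgs2 (-2.63 ± 0.32), Gucy1a1 (-1.91 ± 0.22) and Pde5a (-1.06 ± 0.12) fell, and Ednrb (0.81 ± 0.14), Adm (0.65 ± 0.15) and Ptgs1 (0.63 ± 0.15) rose. Among pericyte and vascular smooth muscle markers, 8 of 11 tested genes fell and 2 rose (8 and 2 adjusted over the list alone, camera adjusted p = 0.000868, and adjusted p = 0.141 with an estimated correlation). Tagln (-1.51 ± 0.12), Cox4i2 (-1.78 ± 0.17), Acta2 (-1.58 ± 0.15) and Mcam (-1.48 ± 0.19) fell, and Pdgfrb (0.63 ± 0.090) and Heyl (0.88 ± 0.22) rose. Among myometrial smooth muscle markers, 8 of 11 tested genes fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 8.61e-05, and adjusted p = 0.141 with an estimated correlation). Mylk (-1.42 ± 0.12), Lmod1 (-2.32 ± 0.21), Myh11 (-2.54 ± 0.30) and Myocd (-1.75 ± 0.21) fell, and the intermediate filament gene Des (0.38 ± 0.16) rose. In edgeR, Des no longer passed without any of 11 libraries (adjusted p of 0.0501 to 0.096).

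**Figure D2:**
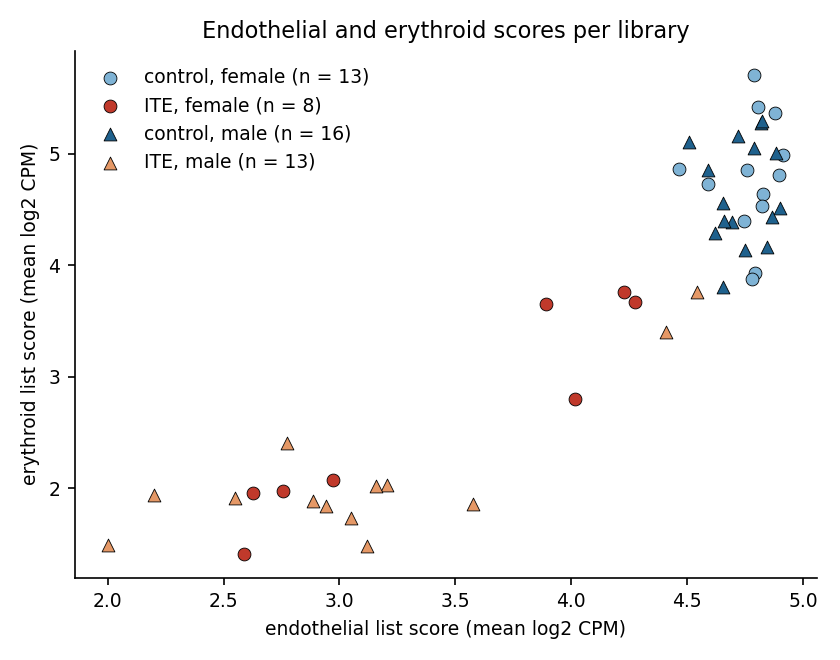
Erythroid against endothelial marker score (mean log2 CPM of the list's genes) of each of the 50 libraries, by group. The 29 control libraries lie together at the upper right and the 21 ITE libraries lie lower on the erythroid axis and run from 2.0 to 4.54 on the endothelial one.

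Many trophoblast endocrine genes rose in male placentas, and transporter and imprinted genes fell in part. Among prolactin family genes, 13 of 21 tested genes rose and none fell (13 adjusted over the list alone, camera adjusted p = 0.000907, and adjusted p = 0.182 with an estimated correlation). Among junctional zone markers, 13 of 20 tested genes rose and none fell (13 adjusted over the list alone, camera adjusted p = 0.000868, and adjusted p = 0.193 with an estimated correlation). Among giant and invasive trophoblast markers, 8 of 12 tested genes rose and none fell (9 adjusted over the list alone, camera adjusted p = 0.00439, and adjusted p = 0.141 with an estimated correlation). Tpbpa went from 12700 ± 2790 to 22100 ± 5620 CPM (0.81 ± 0.14), and Prl2a1 (0.93 ± 0.091), Prl4a1 (0.90 ± 0.11), Prl6a1 (1.24 ± 0.17), Ceacam3 (1.06 ± 0.17), Prl7d1 (1.09 ± 0.19), Plau (0.78 ± 0.13) and Ctsr (0.47 ± 0.094) rose. Among labyrinth trophoblast markers, 6 of 14 tested genes fell and 2 rose (6 and 3 adjusted over the list alone, camera adjusted p = 0.0277, and adjusted p = 0.288 with an estimated correlation). Gcm1 (-2.57 ± 0.35), Slc13a4 (-2.91 ± 0.45), Gcgr (-1.85 ± 0.19) and Slc16a3 (-1.42 ± 0.19) fell, and Ly6e (0.42 ± 0.098) and Ctsq (0.32 ± 0.14) rose. Among nutrient and drug transporters, 10 of 20 tested genes fell and 4 rose (10 and 4 adjusted over the list alone, camera adjusted p = 0.0149, and adjusted p = 0.158 with an estimated correlation). Slc22a3 (-2.60 ± 0.36), Fabp3 (-1.42 ± 0.15) and Slc3a2 (-0.71 ± 0.076) fell, and Slc27a4 (0.66 ± 0.094), Slc38a4 (0.35 ± 0.068), Slc27a1 (0.30 ± 0.10) and Slc6a6 (0.27 ± 0.065) rose. Among imprinted placental genes, 8 of 13 tested genes fell and 2 rose (8 and 2 adjusted over the list alone, camera adjusted p = 0.012, and adjusted p = 0.17 with an estimated correlation). Igf2 went from 2710 ± 209 to 1690 ± 398 CPM (-0.68 ± 0.085), Mest (-1.10 ± 0.14), Igf2r (-0.51 ± 0.069) and Grb10 (-0.53 ± 0.079) also fell, and Cdkn1c (0.27 ± 0.057) and Sfmbt2 (0.31 ± 0.087) rose. In edgeR, Ctsq no longer passed without any of 38 libraries (adjusted p of 0.0503 to 0.131).

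Many immune and stress genes rose in male placentas. Among interferon response genes, 17 of 18 tested genes rose and none fell (18 adjusted over the list alone, camera adjusted p = 2.74e-09, and adjusted p = 0.141 with an estimated correlation). Mx1 (2.77 ± 0.28), Gbp2 (1.78 ± 0.17) and Isg15 (1.35 ± 0.14) were among them. Among inflammatory cytokines and chemokines, 10 of 17 tested genes rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.00183, and adjusted p = 0.17 with an estimated correlation). The monocyte attractant gene Ccl2 (3.27 ± 0.27), Cxcl1 (1.87 ± 0.23) and Vcam1 (1.56 ± 0.16) rose, and Il33 (-0.53 ± 0.17) fell. Among macrophage markers, 10 of 13 tested genes rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.00121, and adjusted p = 0.185 with an estimated correlation). Fcer1g (1.45 ± 0.16), Tyrobp (1.35 ± 0.17) and Cd14 (1.27 ± 0.13) rose, and Cd163 (-2.84 ± 0.33) and Mrc1 (-0.70 ± 0.13), receptors of resident macrophages, fell. Among neutrophil markers, 8 of 9 tested genes rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00795, and adjusted p = 0.185 with an estimated correlation). Itgam (1.45 ± 0.18), Mmp9 (1.27 ± 0.16), S100a8 (1.07 ± 0.18) and S100a9 (0.91 ± 0.16) rose, and Camp (-1.13 ± 0.36) fell. Among immediate early genes, 8 of 12 tested genes rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.0104, and adjusted p = 0.202 with an estimated correlation). Egr1 (1.82 ± 0.20), Egr2 (1.84 ± 0.30), Jun (0.72 ± 0.096) and Zfp36 (0.46 ± 0.076) rose, and Fos (-0.51 ± 0.11) fell. Among unfolded protein response genes, 16 of 16 tested genes rose and none fell (16 adjusted over the list alone, camera adjusted p = 6.88e-07, and adjusted p = 0.141 with an estimated correlation). Ddit3 (0.70 ± 0.066), Hspa5 (0.62 ± 0.095), Calr (0.49 ± 0.056) and Xbp1 (0.43 ± 0.046) were among them. Among circadian clock genes, 8 of 14 tested genes rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00727, and adjusted p = 0.141 with an estimated correlation). Nr1d1 (1.39 ± 0.19), Ciart (1.53 ± 0.24), Per3 (0.88 ± 0.096) and Bhlhe41 (0.51 ± 0.078) rose, and Clock (-0.15 ± 0.049) fell. Among nuclear oxidative phosphorylation genes, 8 of 20 tested genes fell and none rose (8 adjusted over the list alone, camera adjusted p = 0.021, and adjusted p = 0.371 with an estimated correlation). Cyc1 (-0.33 ± 0.045), Ndufs1 (-0.31 ± 0.050), Atp5f1b (-0.33 ± 0.053) and Ndufs3 (-0.33 ± 0.054) fell.

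The remaining lists were not called by camera in male placentas, with adjusted p from 0.176 to 0.754. 4 of 13 mitochondrially encoded transcripts were higher and none lower (4 and 0 adjusted over the list alone). 5 of 7 X-linked genes were higher and 1 lower (5 and 1 adjusted over the list alone), the latter being Uba1 (-0.26 ± 0.062). 9 of 19 matrix genes were higher and 3 lower (9 and 3 adjusted over the list alone), with Timp1 (1.34 ± 0.15) higher and Lama4 (-0.60 ± 0.064) lower. 5 of 11 natural killer cell markers were higher and 1 lower (5 and 1 adjusted over the list alone), with Klrk1 (1.91 ± 0.36) higher and Eomes (-0.52 ± 0.20) lower. 2 of 5 lymphocyte markers were higher and none lower (2 and 0 adjusted over the list alone), the former being Cd8a (0.67 ± 0.27) and Lck (0.62 ± 0.16). 4 of 13 decidual markers were higher and 2 lower (4 and 2 adjusted over the list alone), with Igfbp1 (1.52 ± 0.50) higher. None of 14 yolk sac markers was higher and 6 lower (0 and 6 adjusted over the list alone), among them Apoa2 (-2.66 ± 0.60) and Ttr (-2.14 ± 0.59). 6 of 12 steroid synthesis genes were higher and 2 lower (8 and 2 adjusted over the list alone), with Scarb1 (-1.12 ± 0.12) lower, and 6 of 17 hypoxia genes were higher and 5 lower (6 and 5 adjusted over the list alone). 5 of 18 cell cycle genes were higher and 5 lower (6 and 5 adjusted over the list alone), with Ccna2 (-1.74 ± 0.21) lower. 2 of 8 AhR pathway components were higher and 3 lower (2 and 3 adjusted over the list alone), with Ahr (-0.76 ± 0.10) lower. 1 of 5 Y-linked genes was higher and none lower (0 and 0 adjusted over the list alone), the former being an entry named Ddx3y (0.25 ± 0.11) that female libraries also held. Median and mean differed in sign for cell cycle genes (0.083 and -0.082) and AhR components (0.041 and -0.117), and camera pointed down for hypoxia genes at a median of 0.020. Scaled by total counts, the medians of AhR components, hypoxia and cell cycle genes changed sign in both sexes and that of decidual markers in females, and those of called lists did not. In edgeR, Cd8a no longer passed without any of 10 libraries (adjusted p of 0.053 to 0.116), nor Ddx3y without any of 31 (0.051 to 0.0978).

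Cell types that the dissected tissue could hold were compared by a score per library, the mean log2 CPM of a list's genes. The endothelial score was 4.77 ± 0.123 in control female (SD, n = 13) and 3.42 ± 0.749 in ITE female libraries (n = 8), a difference of -1.36 (two-sided exact permutation test, adjusted p = 4.33e-05 over 26 tests). All 8 ITE libraries lay below the controls. In males the difference was -1.63 (two-sided permutation test, adjusted p = 4.33e-05), with 12 of 13 ITE libraries below the controls. The erythroid score differed by -2.12 in females and -2.52 in males, with 8 of 8 and 13 of 13 ITE libraries below the controls. The raw permutation p of these endothelial and erythroid tests, 9.83e-06 in females and 2e-05 in males, are the smallest that the tests can give. All 26 tests moved single libraries freely. Libraries of 1 run of consecutive label numbers shared a treatment. Their deviations from the group means across genes were more alike than between runs (mean r 0.065 against -0.058). The p of the score tests can therefore be too small, and no score test used runs as units. Myometrial (-0.95 and -1.04), pericyte (-0.73 and -0.88) and labyrinth trophoblast scores (-0.56 and -0.79) were lower with ITE in females and males, with permutation adjusted p of 0.000496 or less. With z-scored genes, the female labyrinth difference did not pass (-0.357, exact permutation adjusted p = 0.0754). Junctional zone (0.62 and 0.52) and giant trophoblast scores (0.68 and 0.55) were higher, with permutation adjusted p of 5.48e-05 or less.

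The macrophage score was higher in male ITE libraries by 0.57 (permutation adjusted p = 4.33e-05), with 12 of 13 above the controls, and in females the difference was 0.15 (exact permutation adjusted p = 0.385). The female ITE scores ran from 2.73 to 4.32, against 2.93 to 3.47 in their controls. In the 6 ITE libraries with the lowest first-component scores, 4 female and 2 male, macrophage scores were 2.73 to 3.51, and in the other 15 they were 3.43 to 4.32. Neutrophil scores differed by 0.22 in females and 0.66 in males (permutation adjusted p = 0.0467 and 0.000104), and natural killer scores by 0.24 and 0.31 (permutation adjusted p = 0.0243 and 0.00506). Lymphocyte scores differed by 0.26 in females and 0.34 in males (permutation adjusted p = 0.0747 and 0.000704). Decidual scores differed by 0.14 and 0.23 (permutation adjusted p = 0.248 and 0.00947), of which the male difference did not pass with z-scored genes (0.251, adjusted p = 0.117). Yolk sac scores differed by -1.01 and -0.62 (permutation adjusted p = 0.26 for each). These scores varied widely between libraries, from 0.84 to 6.92 in control female and 0.29 to 6.52 in ITE female libraries. In males they ran from 0.84 to 6.84 in controls and 3.27 to 5.93 with ITE.

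The responses of female and male placentas, which share no library but share runs of label numbers, were compared gene by gene. Libraries of a run were alike, so the female and male responses are not independent of each other. Of the called genes, 2577 rose in both sexes and 2374 fell in both, where independent sets of those sizes would share 984.9 and 757.9, and 24 went in opposite directions. Across the 15269 genes, which are not independent replicates, the female and male log2 fold changes had a Pearson r of 0.789 and a Spearman rho of 0.757. In the mean of both sexes the largest rises were those of Cyp1a1 (4.72 ± 0.44), Cyp1b1 (4.32 ± 0.22), Il24 (4.15 ± 0.42), Kcng1 (3.998 ± 0.44), Ahrr (3.94 ± 0.21), Ms4a7 (3.44 ± 0.16), Lypd5 (3.27 ± 0.51) and Slc5a8 (3.03 ± 0.40). Without ITE female library 4, Kcng1 was at 3.13 and Lypd5 at 2.31. The largest falls were those of Hbg1 (-3.62 ± 0.42), Tmem255a (-3.53 ± 0.26), Abcc8 (-3.21 ± 0.48), Car1 (-3.18 ± 0.38), Scn4b (-3.17 ± 0.39), Ace (-3.09 ± 0.28), Cldn8 (-3.05 ± 0.51) and Chga (-2.99 ± 0.29). Tnfrsf21 (1.995 ± 0.11) rose, and Mmp14 (-1.10 ± 0.048), Tspan3 (-1.17 ± 0.067), Cavin1 (-1.01 ± 0.060) and Prx (-2.47 ± 0.15) fell, with the smallest p. In edgeR 9193 genes passed an adjusted p of 0.05 in the mean, 4976 higher and 4217 lower, with 401 and 869 changed at least 2-fold. In limma-voom with runs of label numbers as a random block 7421 genes passed. When scaled by total counts, 2882 were higher and 6127 lower. With scores of 4 tissue lists as covariates 335 genes passed in edgeR, and with endothelial and erythroid scores 619, with the limit given for each sex.

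**Figure D3:**
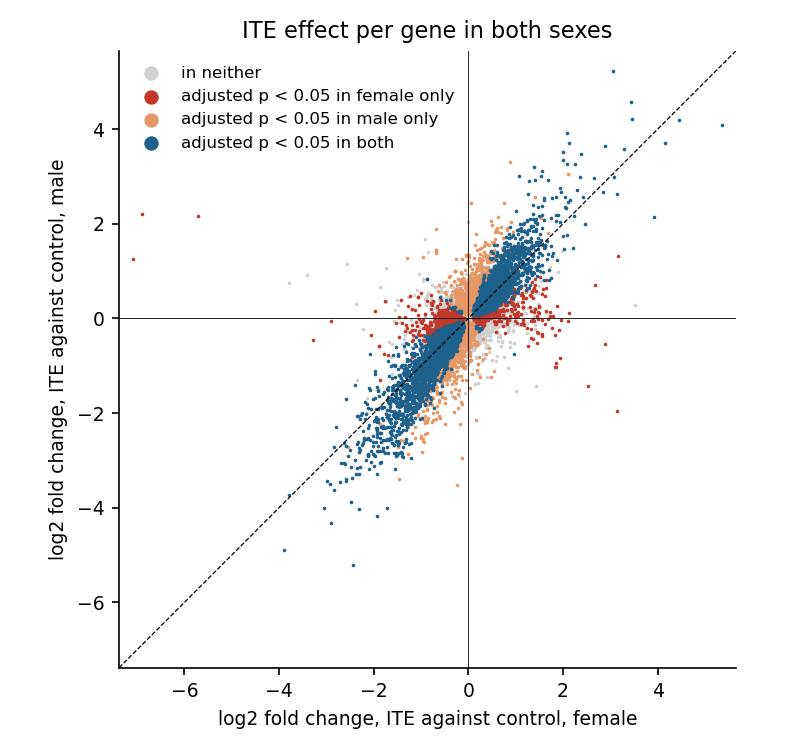
Log2 fold change of ITE against control in male (vertical axis) against female placentas (horizontal axis) for the 15269 tested genes; colours mark genes with adjusted p under 0.05 in one sex, both or neither. Genes called in both sexes lie mostly in the upper right (2577) or lower left (2374).

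In the mean over both sexes, erythroid, endothelial and myometrial lists were again low and giant trophoblast, prolactin and unfolded protein response lists high. Among erythroid markers, 14 of 14 tested genes fell and none rose (14 adjusted over the list alone, camera adjusted p = 3.43e-11, and adjusted p = 0.105 with an estimated correlation). Among endothelial markers, 16 of 18 tested genes fell and 1 rose (16 and 1 adjusted over the list alone, camera adjusted p = 8.7e-08, and adjusted p = 0.141 with an estimated correlation). Among myometrial smooth muscle markers, 8 of 11 tested genes fell and none rose (8 adjusted over the list alone, camera adjusted p = 3.77e-05, and adjusted p = 0.105 with an estimated correlation). Among giant and invasive trophoblast markers, 11 of 12 tested genes rose and none fell (11 adjusted over the list alone, camera adjusted p = 0.000325, and adjusted p = 0.105 with an estimated correlation). Among prolactin family genes, 17 of 21 tested genes rose and none fell (17 adjusted over the list alone, camera adjusted p = 3.87e-06, and adjusted p = 0.105 with an estimated correlation). Among unfolded protein response genes, 15 of 16 tested genes rose and none fell (15 adjusted over the list alone, camera adjusted p = 6.01e-07, and adjusted p = 0.141 with an estimated correlation). Among labyrinth trophoblast markers, 7 of 14 tested genes fell and 3 rose (7 and 3 adjusted over the list alone, camera adjusted p = 0.0503, and adjusted p = 0.329 with an estimated correlation). The preset camera test called 17 lists in females, 22 in males and 21 in the mean, none of which kept its call with an estimated correlation. Random divisions of the libraries gave medians of 5, 7 and 6 called lists, and at most 17, 20 and 21.

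**Figure D4:**
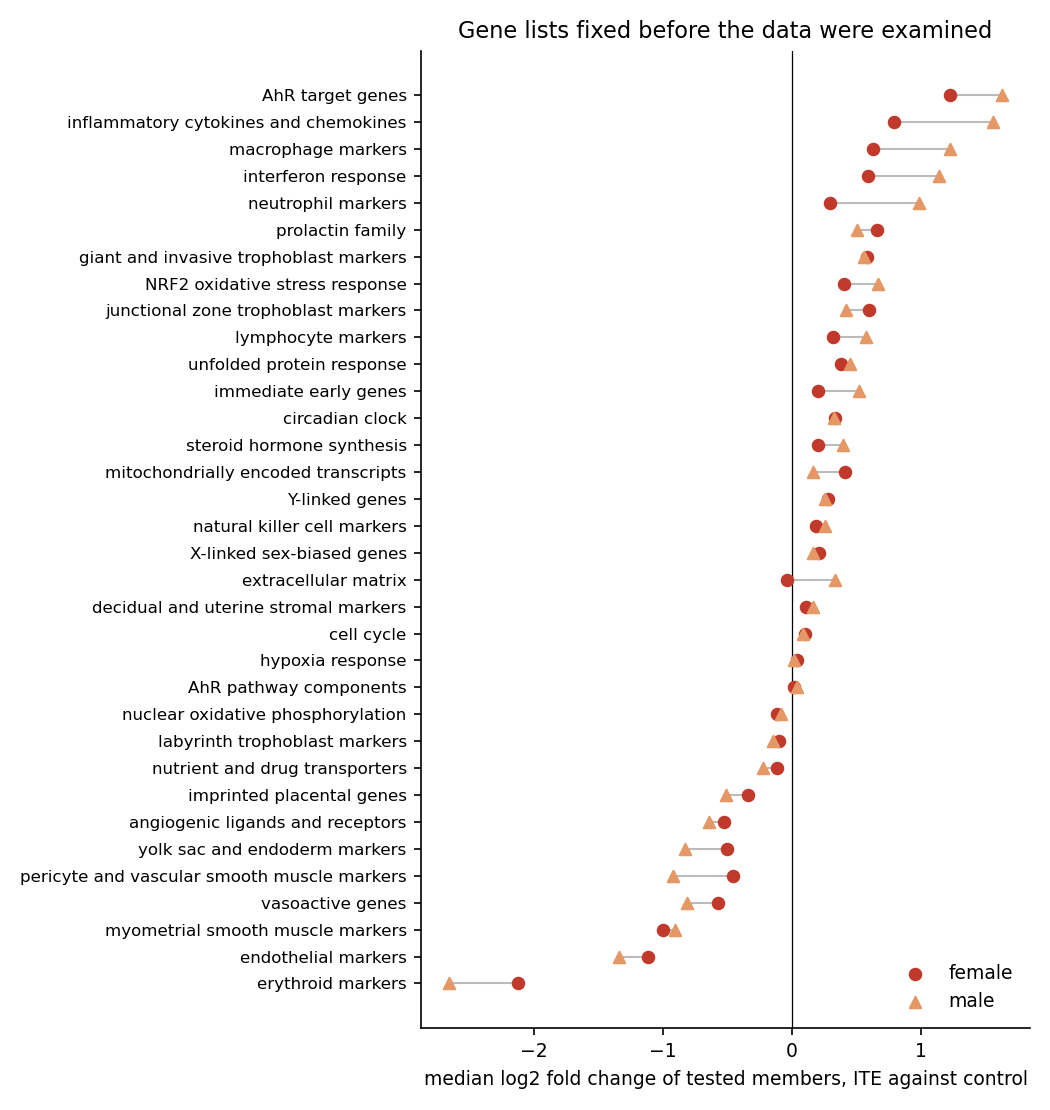
Median log2 fold change of ITE against control over the tested members of each gene list, in female and male placentas. The lowest medians are those of the erythroid list, -2.13 in females and -2.66 in males.

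Whether fetal sex altered the response was tested by the interaction, female minus male. A single gene passed, Psmb9, a subunit of the immunoproteasome. It went from 2.18 ± 0.492 to 2.76 ± 1.15 CPM in females and from 1.71 ± 0.362 to 5.12 ± 1.65 CPM in males, a difference of -1.24 ± 0.23 in log2 fold change (edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.0242). The next by p did not pass (adjusted p = 0.0549 each in edgeR). They were the proteasome gene Psmd3 (-0.46 ± 0.094), Spsb3 (-0.45 ± 0.094), AABR07066188.1 (3.278 ± 0.69), Rgcc (-0.58 ± 0.12) and Ptpa (-0.34 ± 0.073). Leaving out 1 library brought Ptpa past the threshold in 8 cases, Psmd3, Spsb3 and Rgcc in 10 each and AABR07066188.1 in 12. At an unadjusted p under 0.05 there were 2663 genes. The count of 1 ran from 0, without any of ITE female libraries 3, 5, 6 and 7, to 590, without ITE female library 4, and DESeq2 called 116. ITE female libraries 3, 5, 6 and 7 and ITE male libraries 4 and 13 made up the 6 with the lowest first-component scores. Without ITE male library 4 or 13 the count was 113 or 266, and without ITE female library 1, of the other 15, it was 179. In limma with quality weights it was 2318, with the replicate number as a block 326, and in edgeR with counts summed per run and sex 0 (1138 at an unadjusted p under 0.05). As many were called in 12 of 100 arrangements of the sexes, the real one included, so chance was not excluded.

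By list, camera called 10 in the interaction, and none kept its call with an estimated correlation or in fry. Medians were negative, meaning a larger ITE effect in males, for the interferon response (-0.55, camera adjusted p = 1.23e-07, and adjusted p = 0.459 with an estimated correlation) and inflammatory genes (-0.63, camera adjusted p = 0.00023, and adjusted p = 0.459 with an estimated correlation). They were also negative for immediate early genes (-0.35, camera adjusted p = 0.00071, and adjusted p = 0.459 with an estimated correlation) and macrophage markers (-0.53, camera adjusted p = 0.00071, and adjusted p = 0.459 with an estimated correlation). Neutrophil markers (-0.54, camera adjusted p = 0.00569, and adjusted p = 0.459 with an estimated correlation) and matrix genes (-0.19, camera adjusted p = 0.0137, and adjusted p = 0.765 with an estimated correlation) followed. The NRF2 median was -0.27 (camera adjusted p = 0.0406, and adjusted p = 0.747 with an estimated correlation). Medians were positive for mitochondrially encoded transcripts (0.35, camera adjusted p = 8.85e-05, and adjusted p = 0.532 with an estimated correlation) and the prolactin family (0.19, camera adjusted p = 0.016, and adjusted p = 0.747 with an estimated correlation). The erythroid median was 0.42 (camera adjusted p = 0.0406, and adjusted p = 0.801 with an estimated correlation). No member of these lists passed over all genes. Adjusted over the list alone, 8 interferon, 4 inflammatory, 4 immediate early, 4 neutrophil, 3 macrophage and 1 NRF2 gene were lower and 4 mitochondrial transcripts higher. As many lists were called in 35 of 100 arrangements. The 6 ITE libraries with the lowest first-component scores were 4 of the 8 female and 2 of the 13 male ones, and this difference was not separated from sex in the interaction.

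Male and female control placentas were compared to find sex differences without treatment and to check the labels. Ddx3, Kdm5d, Eif2s3y and Usp9y, genes of the Y chromosome, had 82.1 ± 19.2, 28.6 ± 6.64, 31.6 ± 8.08 and 23.6 ± 14.3 CPM in control male libraries (SD, n = 16). In the 21 female libraries their highest counts were 8, 1, 4 and 3. The transcript AC241873.1 was at 19.2 ± 4.57 CPM in control males and 0.0026 CPM in control females. Slc7a15 (1.36 ± 0.31), Atp10b (0.65 ± 0.13), Gpr19 (0.54 ± 0.10) and Nup133 (0.45 ± 0.089) were also higher in males. Female libraries had more of the transcripts AABR07039356.2 (-4.03 ± 0.25) and LOC680227 (-2.76 ± 0.17), and of Taf1 (-0.55 ± 0.052), Eif2s3 (-0.50 ± 0.048), Kdm6a (-0.47 ± 0.049), Fam83f (-0.49 ± 0.089), Rundc3b (-0.55 ± 0.12) and Pin4 (-0.42 ± 0.085). Rps4x stood on 2 table entries, at -0.43 and -0.41. Kdm6a and Eif2s3 are X-linked genes known to escape X inactivation. In edgeR with Benjamini-Hochberg adjustment 39 genes passed, 15 higher and 24 lower in males. Of the lists, 4 of 5 tested Y-linked genes were higher (4 adjusted over the list alone) and 5 of 7 X-linked genes lower (5 adjusted over the list alone). Adjusted over the list alone, 3 of 18 cell cycle genes were also higher. In edgeR, Slc7a15 no longer passed without any of 10 libraries (adjusted p of 0.0509 to 0.0847), nor Rundc3b without any of 14 (0.0502 to 0.0792).

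In 1 library, labelled control male 12, the Y-linked genes were low. They stood at 18.9% (Ddx3), 17.7% (Kdm5d), 10.6% (Eif2s3y) and 4.1% (Usp9y) of the median of the 29 male libraries, with Ddx3 at 15.4 CPM against 70.5 CPM in the next lowest. Without this library, the counts of called genes moved by less than 1.5 times in each of the 6 comparisons.

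Among ITE placentas, male libraries held more of some chemokine and interferon genes, such as Cxcl10, Ccl2 and Gbp5, and less of some red cell genes, such as Slc4a1 and Ahsp. The lists themselves were not tested in this comparison. Cxcl10 was at 17 ± 24.2 CPM in males (SD, n = 13) and 4.93 ± 1.85 CPM in females (n = 8), a male minus female log2 difference of 1.78 ± 0.43 (edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.00663), or 1.15 without ITE male library 3. Ccl2 (1.25 ± 0.31), Gbp5 (1.36 ± 0.33), Spp1 (1.14 ± 0.35), Psmb10 (0.77 ± 0.13), Psmb5 (0.51 ± 0.077) and Psmd3 (0.49 ± 0.073) were higher in males. Slc4a1 (-1.04 ± 0.35), Ahsp (-0.93 ± 0.27), Cd163 (-1.13 ± 0.37), Abcc4 (-1.18 ± 0.22), Taf1 (-0.80 ± 0.061), Kdm6a (-0.47 ± 0.059) and Fmr1 (-0.62 ± 0.076) were lower, and all of these genes were chosen after their values were seen. In edgeR, Ahsp no longer passed without ITE female library 5 or 6 (adjusted p of 0.0599 to 0.107), and Spp1, Cd163 and Slc4a1 without any of 6, 13 and 15 libraries. Of the lists, 6 of 18 interferon, 5 of 17 inflammatory, 4 of 12 immediate early, 4 of 13 macrophage and 3 of 9 neutrophil genes were higher in males (10, 7, 4, 6 and 5 adjusted over the list alone). So were 4 of 5 Y-linked, 3 of 20 nuclear oxidative phosphorylation and 2 of 19 matrix genes (4, 5 and 1). Lower were 5 of 7 X-linked genes, 3 of 14 erythroid markers, 2 of 14 circadian clock genes, 2 of 13 imprinted genes and 1 of 13 macrophage markers (5, 3, 2, 2 and 1 adjusted over the list alone). In each of the other lists at most 1 gene passed in each direction. The 6 ITE libraries with the lowest first-component scores were 4 of the 8 female and 2 of the 13 male ones. In all, 1800 genes passed, 914 higher and 886 lower in males, with 77 and 70 changed at least 2-fold. This fit shared its spread with the controls, which were tighter along the first component, so its SE and p can be too small here. When only the ITE groups were fitted, 803 genes passed. The labels number the libraries in series, in alternating runs of control and ITE, and within the 4 ITE runs that hold both sexes (13 libraries) 19 genes passed and 1223 had an unadjusted p under 0.05. The count was 39 with counts summed per run and sex, 975, 843 and 2931 without ITE female library 5, 7 and 4, and 4493 in limma with quality weights.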

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

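The tests of the endothelial and erythroid pattern, the counts over random arrangements of the libraries, the sums per run and the fit with runs as a fixed term were chosen only after the result was seen.

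Endothelial and erythroid transcripts were lower in ITE libraries by unequal amounts, with endothelial scores at -1.356 in females and -1.628 in males relative to controls, and erythroid scores at -2.12 and -2.52. Less fetal blood in the tissue as the whole cause is argued against by the endothelial falls, and control libraries with ITE labels by Cyp1b1 and Ahrr, which stood above the highest control in 21 and 21 of 21 ITE libraries. A smaller share of labyrinth in the sampled tissue cannot be told apart, because 4 of 14 labyrinth trophoblast markers (Gcm1, Slc13a4, Gcgr and Slc16a3) fell by at least the mean of the endothelial ones (-1.07 and -1.305) while others rose. As a whole, the endothelial score fell further than the labyrinth one, by -0.797 in females (two-sided exact permutation p = 4.91e-06) and -0.84 in males (permutation p = 1e-05), the smallest p that these tests of the absolute difference can give. Both tests moved single libraries and ignored the runs of label numbers, so their p can be too small. Fewer vessels and blood cells in the treated placentas stays open beside a smaller share of labyrinth. Dissection and litter also stay open, which the labels do not give and which were not tested.

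Between male and female ITE libraries 1800 genes differed, while 39 did so between control libraries. A general difference in how far the ITE response went in each sex, alike for all genes, is argued against. Of the 1800 genes, 54.1% had the sign of the mean ITE effect. Over all genes the sex difference and the mean ITE effect had a Pearson r of 0.224. Signs cannot decide on extents that differ between gene groups. The 6 ITE libraries with the lowest first-component scores had the highest Cyp1a1 but the smallest endothelial and erythroid falls. For single groups such as red cell and macrophage genes an unequal extent stays open, because 4 of 8 female but 2 of 13 male ITE libraries were among these 6. Likeness of libraries with neighbouring label numbers cannot be told apart from sex. Within the 4 ITE runs that hold both sexes the fold changes shrank to a median ratio of 0.548 and 19 genes passed, over 13 libraries only. The direction stayed in 1750 of 1766 genes. These genes were selected for a difference in the same libraries, which can by itself shrink the ratio and keep the direction, so neither value decides. A difference between the sexes in the response itself stays open, and its direct test is the interaction.

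The library labelled control male 12 held few Y-linked transcripts, at 4.1% to 18.9% of the male median. RNA of a female placenta in the library is argued against by the transcripts with the largest female excess in controls, since AABR07039356.2 was at 11.3% and LOC680227 at 18.5% of the control female mean. Loss of the Y chromosome in part of a male placenta cannot be told apart from other causes, because AABR07039356.2 (0.602 CPM) lay just above the highest other control male (0.554 CPM) and LOC680227 (0.792 CPM) within their range (up to 1.0 CPM). No other biological explanation was tested.

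In ITE female library 7, Tiparp was at 5.02 log2 CPM, far from the other 7 libraries of its group (5.36 to 5.66). In ITE female library 4, Mmp9 was at 4.15 log2 CPM against 2.69 to 3.29 in the others. In ITE female library 1, Rgcc was at 5.87 log2 CPM against 5.33 to 5.55 in the others. These were 3 of 157 measures tested (1.9%), where chance alone gives about 1 in 20.

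The female minus male ITE effect differed from 0 for 1 gene, Psmb9 (-1.237 ± 0.23, log2). As many genes were called in 12 of 100 arrangements of the sexes within treatments, so chance is not excluded, and another arrangement called 2329, which points to a structure of the libraries.

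The arrangements moved single libraries and ignored the runs of label numbers, so chance is excluded below only for free arrangements. For ITE against control it is excluded in females (6484 genes, reached in 1 of 100 arrangements, the real one, with 3 in the highest other), males (8173 genes, 1 of 100, highest other 2530) and their mean (9193 genes, 1 of 100, highest other 24). With counts summed per run and sex 5236, 5586 and 7862 genes passed. Between males and females, chance is excluded for the 39 genes in controls (1 of 100, highest other 1). The 1800 in ITE were reached in 2 of 100 arrangements, with 3017 genes in the highest other, and 803 passed when only the ITE groups were fitted. Free arrangements cannot decide here, because libraries of a run were alike, so chance is not excluded for the 1800. The 3017 genes point to a structure of the libraries, and with the runs as units or as a fixed term 39 and 19 genes passed in ITE. For gene lists the arrangements reached the count in 2 of 100 in females (17 lists, highest other 17) and 1 of 100 in males (22 lists, highest other 20). In the mean they did so in 2 of 100 (21 lists, highest other 21). Each run held a single treatment and free arrangements broke up the runs, so they cannot exclude chance for these lists. Nor is chance excluded for the 10 lists of the interaction (35 of 100, highest other 18). The other arrangements called medians of 5, 7, 6 and 8 lists, and with an estimated correlation camera called 0 lists in each of the 4 comparisons, where fry called 25, 28, 28 and 0.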

How the results depend on the processing

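Scaling by total counts, leaving out the library labelled control male 12, endothelial and erythroid scores as covariates, sums per run and runs as a fixed term were chosen only after the data were seen. The counts of called genes stayed within 1.5 times the reported ones under 11 of 13 alternatives in females (4830 to 6672), 11 of 13 in males (5586 to 8820), 10 of 12 in their mean (6407 to 9522), 11 of 13 between control sexes (30 to 57) and 9 of 14 between ITE sexes (1455 to 2483). The interaction did so under 5 of 12 (1 each). Called lists did so under 7 of 9 each, at 16 to 25 in females, 21 to 28 in males, 19 to 28 in the mean and 7 to 10 in the interaction. At these library numbers and depth, 64.2% of simulated 1.5-fold interactions were recovered, with independent libraries and 1 spread per gene for all groups. Real ITE libraries were more spread than controls, with a first-component SD of 29.6 against 6.4 in females. The rate need therefore not hold for these data, and depth alone was not varied.

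The interaction called 5 genes with no filter, 4 at a mean of 5 CPM or more, 6 by total counts, 116 in DESeq2, 2318 with quality weights and 0 in edgeR with counts summed per run and sex (1138 at an unadjusted p under 0.05). Control sexes gave 25 genes at 5 CPM or more, where fewer genes were tested, and 76 with runs as a random block. ITE sexes gave 803 with only the groups compared, 716 with runs as a random block, 4493 with quality weights, 39 with sums per run and 19 with runs as a fixed term. The fits of ITE alone and of sums held fewer libraries or units. The fit of ITE alone also took its spread without the controls, which were tighter along the first component than ITE libraries. Which of these, or what else, moved the counts was not tested. With tissue scores (decidua, myometrium, yolk sac, junctional zone) as covariates the counts were 460 in females, 170 in males and 335 in the mean, with 6, 10 and 7 lists. With endothelial and erythroid scores they were 809, 305 and 619. Of these scores the myometrial, junctional zone, endothelial and erythroid ones differed by treatment in both sexes and the decidual one in males, while yolk sac scores did not pass (permutation adjusted p = 0.26 in each sex). The counts with covariates therefore cannot part tissue make-up from the ITE effect. With an estimated correlation camera called 0, 0, 0 and 0 lists in females, males, the mean and the interaction, and fry 0 in the interaction. With z-scored genes the decidual difference in males (0.251) and the labyrinth difference in females (-0.357) no longer passed. DESeq2 left the adjusted p undefined for 3452 to 11323 of 25383 genes by its own filter, 0 of them called in the reported fits. In a replicate block the counts were 6567, 7949, 9119, 326 for the interaction, 30 and 2483. The labels do not say that equal replicate numbers pair placentas. Of 21 control and ITE pairs of equal number, 9 correlated above 0.1 (range -0.228 to 0.223). In 7 of the 21 the ITE library of the same number was the best match, so a shared structure was not excluded.

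Leaving out 1 library at a time gave 5729 to 6558 genes in females, 7896 to 8365 in males, 8952 to 9268 in the mean, 32 to 45 between control sexes, 843 to 2931 between ITE sexes and 0 to 590 for the interaction. The ITE sexes moved by over 1.5 times without ITE female library 4 (2931), 5 (975) and 7 (843). The interaction moved without ITE female library 1 (179), 2 (16), 3, 5, 6 and 7 (0 each) and 4 (590), and without ITE male library 4 (113), 5 (10), 11 (15), 12 (6) and 13 (266). It also moved without control male library 5 (4), 9 (2), 11 (10) and 15 (2), and control female library 8 (5).

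Of 3700 values of named genes over 13 alternatives, 3228 kept direction and side of the threshold, 387 no longer passed, 21 newly passed and 64 reversed, 0 of the latter past the threshold. The reversals came with covariates. Some reversed genes are members of a score used as covariate. They are Tpbpa and Prl8a5 (junctional zone), Mylk, Myocd and Myh11 (myometrial) with tissue scores, and Car1 (erythroid) with endothelial and erythroid scores. A score that holds the gene and differs by treatment takes up part of its effect, so their reversals decide nothing about these genes. With tissue scores the log2 fold changes in females were Kcng1 -1.143, Hbg1 0.348, Txnrd1 -0.117, G6pd -0.08, Prdx1 -0.283, Vegfa 0.04, Pde5a 0.287, Eng 0.147, Sox17 0.159, Mylk 0.072, Myocd 0.134, Tpbpa -0.135, Prl8a5 -0.05, Isg15 -0.016, Ddit3 -0.046, Eif2s3 -0.006. In males they were Kcng1 -0.01, Lypd5 -0.694, Pde5a 0.012, Eng 0.299, Ptprb 0.458, Mcam 0.201, Myh11 0.175, Tpbpa -0.225, Igf2 0.127, Mest 0.061, Hspa5 -0.102. In the mean they were Il24 -0.421, Kcng1 -0.576, Lypd5 -1.052, Txnrd1 -0.008, Gclc 0.128, G6pd -0.143, Pde5a 0.149, Eng 0.223, Sox17 0.292, Notch3 0.055, Myh11 0.351, Tpbpa -0.18, Slc22a3 0.272, Igf2 0.151, Mest 0.171, Igf2r 0.018, C1qb -0.081. With endothelial and erythroid scores they were, in females, Kcng1 -0.291, Hbg1 0.818, Txnrd1 -0.002, G6pd -0.034, Prdx1 -0.287, Isg15 -0.023. In males they were Car1 0.075, Slc7a5 0.007, Mcam 0.072, Slc16a3 0.057, Atp5f1b 0.005, and in the mean Lypd5 -0.076, Hbg1 0.397, Car1 0.39, G6pd -0.11, Slc7a5 0.017, Slc22a3 0.078, C1qb -0.157, Itgam -0.108, Atp5f1b 0.001.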

Other observations

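The gene families, the library sets and the tests of those sets were chosen only after the result was seen. Metallothionein genes, which bind metal ions, rose with ITE, 2 of 3 in females and 3 of 3 in males, with Mt1 at 2.05 and 2.57 and Mt2A at 1.75 and 2.12 (log2 fold change in females and males). Glutathione transferase genes rose in 8 of 16 cases in each sex and fell in 1 and 4, among them Gsta5 (2.42 and 2.56), Gstm5 (1.16 and 1.42) and Gstp1 (0.82 and 1.0). Amino acid transporter genes of the Slc7 family fell, 7 of 10 in females and 9 of 10 in males, with Slc7a6 at -1.38 and -2.07 and Slc7a2 at -1.40 and -2.25. Slc7a11, a cystine transporter gene, rose (0.67 and 0.99, in females not past the threshold without ITE female library 4). Of 22 tested RT1 genes of the major histocompatibility complex, 3 rose and 3 fell in females and 11 rose and 4 fell in males. Their medians were 0.065 and 0.607, the female one turning to -0.064 when scaled by total counts. Reads shared between RT1 paralogs make single members uncertain.

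Proteasome subunits rose in 32 of 36 cases in males (median 0.243) and 6 of 36 in females (median 0.077, or -0.055 when scaled by total counts). The inducible subunits were at 0.185 and 1.151 (Psmb8), 0.341 and 1.578 (Psmb9) and -0.044 and 0.648 (Psmb10) in females and males. The family was picked because Psmb9 and Psmd3 had some of the smallest p of the interaction, so a test of the interaction over its members decides nothing. Of the single subunits, Psmb9 passed in the interaction over all genes.

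The 6 ITE libraries with the lowest first-component scores and the other 15 were not defined by the labels. They were parted at the largest gap in those scores, so ranges of expression in the sets follow in part from that choice. Macrophage scores were 2.73 to 3.51 in the 6 and 3.43 to 4.32 in the 15. Over the 15, the endothelial score and the log2 CPM of Cyp1a1 had a Pearson r of 0.523 (permutation p = 0.047, adjusted p = 0.094 over 2 relations) and a Spearman rho of 0.664 (permutation p = 0.00843, adjusted p = 0.0169), and r was 0.704 without the 2 libraries farthest from the median endothelial score. Over the 6, r was 0.027 (exact permutation p = 0.96, adjusted p = 0.96) and rho 0.029 (exact permutation p = 1.0), and r was 0.895 without 2 libraries. Of the spread of the 21 ITE libraries, 32.2% of the endothelial, 50% of the erythroid and 26% of the macrophage score lay between the 7 ITE runs of label numbers (permutation p = 0.403, 0.0944 and 0.572). Over all 14 runs, deviations from the group means correlated more between libraries of the same run (mean r 0.065) than between runs of the same treatment (-0.058), with one-sided permutation p = 1e-04, the smallest that 10000 resamples can give. The 10 most abundant transcripts of a library took 22.1 ± 1.836% of counts in control female, 25.4 ± 2.042% in ITE female, 22.4 ± 1.433% in control male and 26.9 ± 2.048% in ITE male libraries (SD).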
